A study of Mus musculus with 9 samples.

How the data were processed

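Gene expression was measured by RNA sequencing in whole eyeballs of female BALB/C mice, an albino inbred strain. There were 3 groups of 3 libraries. The CON group was not injected and was given water, the DES group was injected with scopolamine and given water, and the T.chuii group was injected with scopolamine and fed 300 mg/kg of the green microalga Tetraselmis chuii. Treatment lasted 2 weeks from 6 weeks of age, and tissue age was postnatal day 56, per the labels. Scopolamine blocks muscarinic acetylcholine receptors and is used to induce dry eye. Groups were taken from the sample titles. The labels do not state that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical.

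Libraries were made from total RNA with a stranded mRNA kit, per the labels' protocols. Reads were handled with FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2 2.3.4.1 and StringTie 2.1.3b against the mouse build mm10, per the submitters' processing notes. The parameters, the counting step and its strand setting were not given in the sources used here, so reads of overlapping or antisense genes and of near-identical paralogs may have been divided between them. The deposited tables hold a read count and an FPKM value (fragments per kilobase of transcript, scaled to library size) for each gene and library, per the file headers. Each table had 22587 genes in the same order. The transcript field of a row spans a varying number of cells, so the count and the FPKM were read from the right end of each row. All counts were whole numbers, and library totals lay between 39.1 and 64.6 M reads. No gene had a count of 0 in any library, and the smallest count was 1. How rows were filtered is not given in the sources used here. Of the 16 listed lens crystallins, 10 were not analysed here, and a gene switched from 0 to a high level could not have been found.

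Gene IDs were matched to the RefSeq gene table of GRCm38.p6, the same assembly as mm10, which held 22534 of them, and gene coordinates are from that table. The symbol was identical for 21460. Mitochondrial genes carry the names used in the tables, such as COX1 and CYTB.

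Genes were kept where the counts scaled to library size (CPM) reached the equivalent of 10 reads in a library of median size in at least 3 libraries, with at least 15 reads in total, which left 21287 genes. Libraries were scaled by trimmed means of M-values, computed by code written for this purpose. The deposited counts were tested with limma-voom (limma 3.58.1 in R 4.3.3), with all 9 libraries in 1 fit, 3 group means, 6 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05, two-sided. A quasi-likelihood count test had been planned as the main test with a second count test as an alternative. Neither was run, because a check of columns by header position did not accept the irregular rows as counts. The counts read from the right end of each row would have allowed both. Limma-voom, which is made for counts, was used in their place. This replaced the main test after the tables had been seen. CPM values in the text are scaled by the same factors and given as mean ± SD (n = 3). Changes are log2 fold changes ± standard error. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

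The test was run on simulated counts for the 21287 genes with 200 changed genes. With independent noise as large as that measured within groups, the simulated DES vs CON comparison recovered 2 of 50 genes changed 2-fold, 20 of 50 changed 4-fold and 33 of 50 changed 8-fold, with 2 false calls. For simulated T.chuii vs DES these numbers were 4, 25 and 37 of 50, with 3 false calls. For simulated T.chuii vs CON they were 1, 24 and 37 of 50, with 1 false call. With the noise of the quietest 10% of genes, 36, 49 and 49 of 50 were recovered in simulated DES vs CON, and 43, 49 and 49 of 50 in each of the other 2, with 5, 4 and 5 false calls.

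The 42 gene lists, covering cell types of the eye and of adjoining tissue, dry eye inflammation and stress pathways, were fixed before the data were examined, as were the groups, the comparisons, the rule for named genes and the other settings to be tried. Of 666 list entries, 575 were found in the tables. Lists with at least 5 tested genes were tested against the other genes with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over lists. Camera with an estimated correlation and fry were run beside it. Shares of reads held by 5 lists were compared by exact two-sided permutation, for which 3 against 3 libraries allow no p under 0.1, and adjusted over 15 comparisons. Wilson 95% intervals of a share were at most 0.0065 percentage points to either side and cover counting error only.

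Named genes were to be the 10 with the largest change in each direction among protein-coding genes past the threshold, with groups that do not overlap and a mean of at least 5 CPM in the higher group. Where fewer than 10 passed, those with the smallest unadjusted p followed, said to have missed the threshold. Up to 4 members of each list past the threshold and a fixed dry eye panel were added. From that panel Il6 and Muc16 were not analysed here. The other settings fixed beforehand were other scalings, other filters, removal of the lens crystallin, muscle and blood lists before scaling, other variance models, a fit of only the 6 libraries compared, library weights, a replicate block and the omission of each library. The labels do not say that a replicate number marks a shared animal, batch or day. Deviations from group means correlated above 0.1 in all 3 same-numbered pairs of DES and T.chuii libraries (0.56, 0.34 and 0.17), although DES 2 correlated more with T.chuii 3 (0.46) than with T.chuii 2, and in 2 of 6 pairs with CON. A fit of DES and T.chuii libraries with the number as a block was therefore added, as were shares compared within these pairs. These pairs were thus chosen from the data. DES 1 and T.chuii 1 also correlated with CON 2, which has another number (0.45 and 0.46). Covariates for tissue markers, FPKM values with limma-trend, library totals with no scaling factors and the joint omission of libraries rich in corneal transcripts were added after seeing the data.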

Results

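RNA from whole eyeballs was compared between mice that were not injected (CON), mice injected with scopolamine to induce dry eye (DES), and injected mice fed Tetraselmis chuii (T.chuii), with 3 libraries per group. Library totals were 39.1, 64.6 and 56.5 M reads for CON, 51.6, 53.2 and 39.5 M for DES, and 47.1, 44.4 and 50.4 M for T.chuii. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom of any pair being 32.7.

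Libraries differed in the shares of reads held by lists of tissue genes. Lens crystallins, the main proteins of the lens, held 0.0287%, 0.0201% and 0.0248% of reads in the CON libraries, 4.07%, 0.0408% and 3.47% in DES, and 2.53%, 5.86% and 1.21% in T.chuii. Fast skeletal muscle genes held 0.31%, 0.0919% and 0.203% in CON, 0.932%, 0.304% and 0.177% in DES, and 1.75%, 0.92% and 0.417% in T.chuii. Rod phototransduction genes held 4.5%, 2.09% and 4.57% in CON, 2.09%, 5.84% and 4.46% in DES, and 1.2%, 4.36% and 5.02% in T.chuii. The libraries CON 2, DES 1 and T.chuii 1 were low in rod genes and had the highest ratios of corneal epithelium to rod reads, 3.44, 2.29 and 3.46, against at most 0.775 in the other 6. The first principal component, with 37.1% of the variance, placed these 3 libraries apart from the rest.

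**Figure D1:**
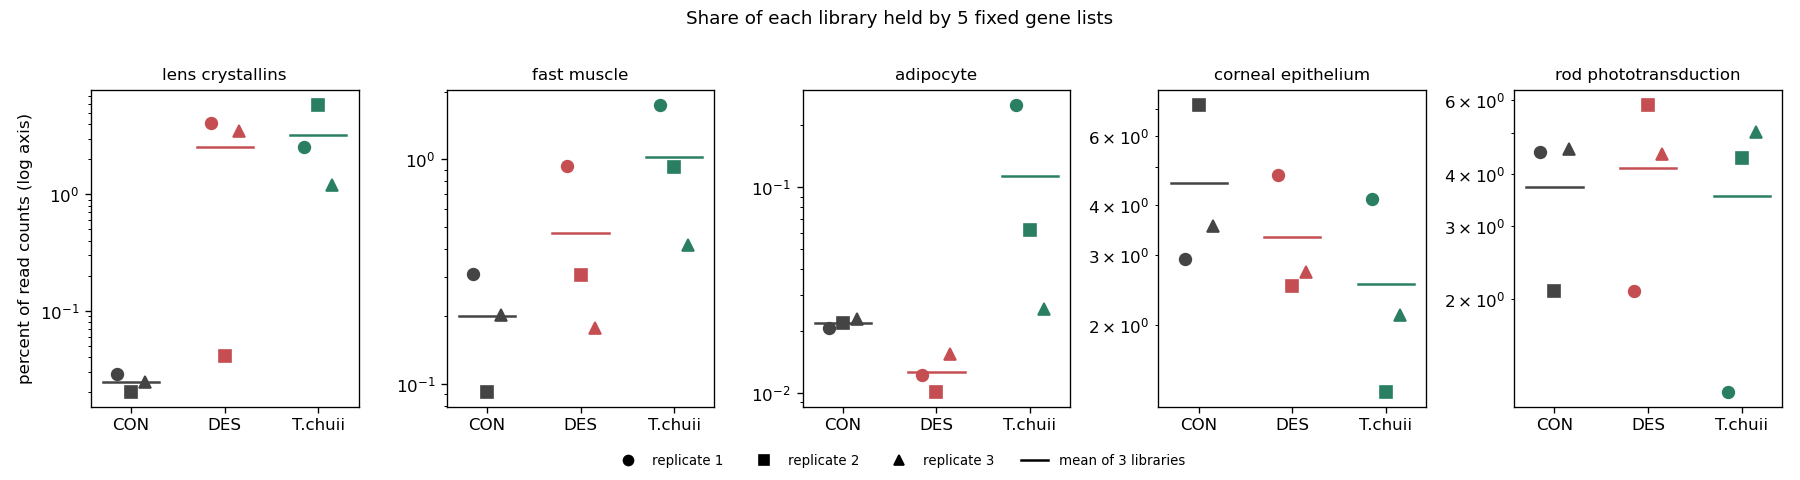
Percent of read counts (log axes, which differ between panels) held by 5 fixed gene lists in each of the 9 libraries, with points for libraries and lines for group means. Lens crystallins lay at 0.0408% in DES 2 and at 3.47% or more in the other 2 DES libraries, and CON 2, DES 1 and T.chuii 1 were low in rod genes.

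Of the 5 lists planned for comparison of shares, lens crystallins and both muscle lists accounted for the 4 of 15 comparisons in which groups did not overlap. Lens crystallins averaged 0.0245% ± 0.00428 in CON, 2.53% ± 2.17 in DES and 3.2% ± 2.4 in T.chuii (SD, n = 3), and both injected groups lay above CON (exact permutation p = 0.1, the smallest possible, adjusted p = 0.375). Fast muscle was 1.03% ± 0.676 in T.chuii against 0.202% ± 0.109 in CON, and slow muscle 0.25% ± 0.192 against 0.0594% ± 0.019 (SD, n = 3, exact permutation p = 0.1 and adjusted p = 0.375 for each). Rod and erythroid shares overlapped between all groups. Within same-numbered DES and T.chuii libraries, fast and slow muscle were higher in T.chuii in 3 of 3 pairs, by a mean log2 ratio of 1.25 (SD 0.34) and 1.06 (SD 0.2), each at exact p = 0.25, the smallest possible with 3 pairs (adjusted p = 0.625). Lens crystallins were higher in 1 of 3 pairs (1.65, SD 4.79, exact p = 1), rods in 1 of 3 (-0.35, SD 0.49, exact p = 0.5) and erythroid genes in 2 of 3 (0.47, SD 1.55, exact p = 0.75).

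The comparison of DES with CON asks what scopolamine injection changed in the eye. CON was not injected, so effects of the drug and of the injection itself cannot be told apart. No single gene passed the test. The protein-coding genes with the smallest p among those higher in DES were lens genes: Cryaa, which encodes alpha-A crystallin, was at 16100 ± 14400 CPM in DES and 4.41 ± 7.17 in CON (log2 change 12.17 ± 2.05), and Crybb1 at 1330 ± 1180 and 0.637 ± 0.511 (9.38 ± 2.35). The genes with the smallest p among those lower in DES included Ptgs2, the inducible cyclooxygenase, at 1.47 ± 0.375 CPM against 5.32 ± 2.71, the activin antagonist Fst at 16.4 ± 2.8 against 62.9 ± 44.5, and the collagen gene Col1a1 at 28.2 ± 7.17 against 84 ± 34.6. All of these missed the threshold.

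Cryaa lies at chromosome 17, 31677931 to 31681730, and Col1a1 at chromosome 11, 94936224 to 94953042 (mm10). Other lens genes with higher means in DES were Cryba4 (log2 change 8.67 ± 2.07), Crybb3 (9.07 ± 2.51) and the galectin-related gene Grifin (7.67 ± 2.55). Cryba4 (chromosome 5, 112246492 to 112263625) overlaps Crybb1 (112254563 to 112269585), so the division of reads between them is uncertain. Outside the lens lists, Npl, which acts on sialic acid, stood at 24.7 ± 10.6 CPM against 8.88 ± 2.81, the protease gene Adamts18 at 7.93 ± 5.51 against 2.09 ± 0.212, and the endothelial gene Esm1 at 5.54 ± 3.09 against 2.16 ± 0.692. Lower means were also found for Angptl7 (-1.85 ± 0.51), Fgf10, a mesenchymal growth factor (-1.53 ± 0.48), Igfbp2 (-1.58 ± 0.53), Matn4 (-1.43 ± 0.47), Pou3f3 (-1.29 ± 0.36), Srpx2 (-1.24 ± 0.41) and Zfp335 (-0.99 ± 0.3). None of these passed the test.

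Among the fixed lists, all 6 lens crystallins tested and all 9 other lens fibre genes had higher means in DES, and 5 crystallins passed when adjusted over the list alone and 0 over all genes. The crystallin list passed camera (adjusted p = 2.38e-19), but not with an estimated correlation (adjusted p = 0.291 with an estimated correlation). All 19 fast muscle genes (median log2 change 1.06) and all 13 mitochondrially encoded genes (median 0.62) had higher means in DES. Camera gave adjusted p = 2.31e-13 and 3.7e-10 for these lists, and adjusted p = 0.405 with an estimated correlation for both. The call of the mitochondrially encoded list was lost without CON 2 (camera adjusted p = 0.0685), and fast muscle turned to the other direction without CON 2, DES 1 and T.chuii 1 together (camera adjusted p = 0.896). COX1, a subunit of cytochrome c oxidase, was at 4350 ± 879 CPM against 2670 ± 814.

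Of 16 keratocyte and scleral matrix genes, 15 had lower means in DES (median -0.73, camera adjusted p = 2.25e-12, adjusted p = 0.405 with an estimated correlation). Col1a2 was at 125 ± 30.5 CPM against 324 ± 184 and Col6a1 at 38.1 ± 10.2 against 101 ± 66.3. Lower means also prevailed in the list of retinal stress and complement genes, 16 of 18, with A2m at 125 ± 18.2 CPM against 518 ± 498, and among glucocorticoid-responsive genes, 12 of 14, with the chaperone gene Fkbp5 at 24.6 ± 6.72 against 57.6 ± 28.2. These lists had camera adjusted p = 1.01e-06 and 5.95e-05, and adjusted p = 0.405 with an estimated correlation for both. Of 15 ion and water transport genes 12 had lower means, among them the sodium channel subunit Scnn1b at 0.64 ± 0.352 CPM against 2.57 ± 1.81 and the water channel Aqp1 at 48.4 ± 3.89 against 83.7 ± 36.2 (camera adjusted p = 0.000149, adjusted p = 0.405 with an estimated correlation). That call was lost without CON 2 (camera adjusted p = 0.0956). All 14 corneal epithelium genes had lower means (median -0.39, camera adjusted p = 0.00707, adjusted p = 0.685 with an estimated correlation). Without CON 2 that list turned to the other direction (camera adjusted p = 0.835).

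The dry eye panel showed no gene past the threshold. Tnf was at 4.26 ± 0.836 CPM in DES against 6.11 ± 4.02 in CON, Il1b at 1.61 ± 0.41 against 3.09 ± 1.07, Ccl2 at 2.53 ± 1.41 against 3.31 ± 3.96, Cxcl10 at 0.532 ± 0.237 against 0.409 ± 0.157, Icam1 at 13.3 ± 2.87 against 14.1 ± 4.67 and Mmp9 at 2.8 ± 1.32 against 3.42 ± 0.465. The stromelysin gene Mmp3 was at 102 ± 54 against 192 ± 31.8 (log2 change -1.02 ± 0.36). Mucin genes had values of 31.7 ± 12.6 and 31.7 ± 10.1 for Muc1, 124 ± 35.5 and 140 ± 94.4 for Muc4, and 37.5 ± 54.3 and 15.6 ± 15.1 for Muc5ac. The corneal keratin Krt12 was at 13800 ± 6760 and 19700 ± 12300, Aqp5 at 2680 ± 1380 and 4490 ± 3100, the muscarinic receptor Chrm3 at 1.9 ± 0.512 and 1.64 ± 0.447, Hmox1 at 30.5 ± 21.2 and 17.1 ± 13.6, and Nqo1 at 113 ± 38.2 and 118 ± 50.9. The cytokine list was not past the threshold (15 of 21 lower, camera adjusted p = 0.0532, adjusted p = 0.685 with an estimated correlation), but it passed in the lower direction in 7 of 13 other settings. Not past it either were the antioxidant list (13 of 25 lower, 0.839) and the mucin and goblet cell list (8 of 14 lower, 0.839).

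In the DES vs CON comparison limma-voom called 0 of 21287 genes at adjusted p 0.05, with 235 genes at an unadjusted p under 0.05, and limma-trend on FPKM also called 0, with 310. The 235 were 1.1% of genes, below the share of 0.05 that unchanged genes would give on average. Groups did not overlap for 3.7% of genes, where chance gives 10%. Without DES 2, the DES library with few lens reads, 15 genes passed, all higher in DES, and named lens genes were among them (Cryaa, Cryab, Cryba4, Crybb1, Crybb3, Crygn, Gja3, Grifin, Lim2). Camera passed 18 of 42 lists, 8 higher and 10 lower in DES, and 0 with an estimated correlation, while fry passed 0 (smallest adjusted p = 0.813). Of the 18 lists, 6 kept their call with each library left out in turn: lens crystallins, other lens genes, fast muscle, matrix, retinal stress and complement, and glucocorticoid response.

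The comparison of T.chuii with DES asks what feeding the alga changed in injected mice. No single gene passed the test. Gfap, the intermediate filament gene of astrocytes and reactive Müller glia, was at 37.4 ± 11.3 CPM in T.chuii and 8.73 ± 3.18 in DES (log2 change 2.14 ± 0.46). Its lowest T.chuii library lay above its highest DES library. The rule for genes named by smallest p asks for groups without overlap, which 4.8% of all genes showed. Genes of fat cells had higher means in T.chuii: the adipokine genes Cfd (216 ± 260 against 2.48 ± 3.32 CPM) and Retn (41.8 ± 46.5 against 1.74 ± 1.17), and the fatty acid binding gene Fabp4 (399 ± 485 against 27 ± 14.5). The myelin gene Mobp was at 106 ± 116 against 0.788 ± 0.524. All of these missed the threshold.

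**Figure D2:**
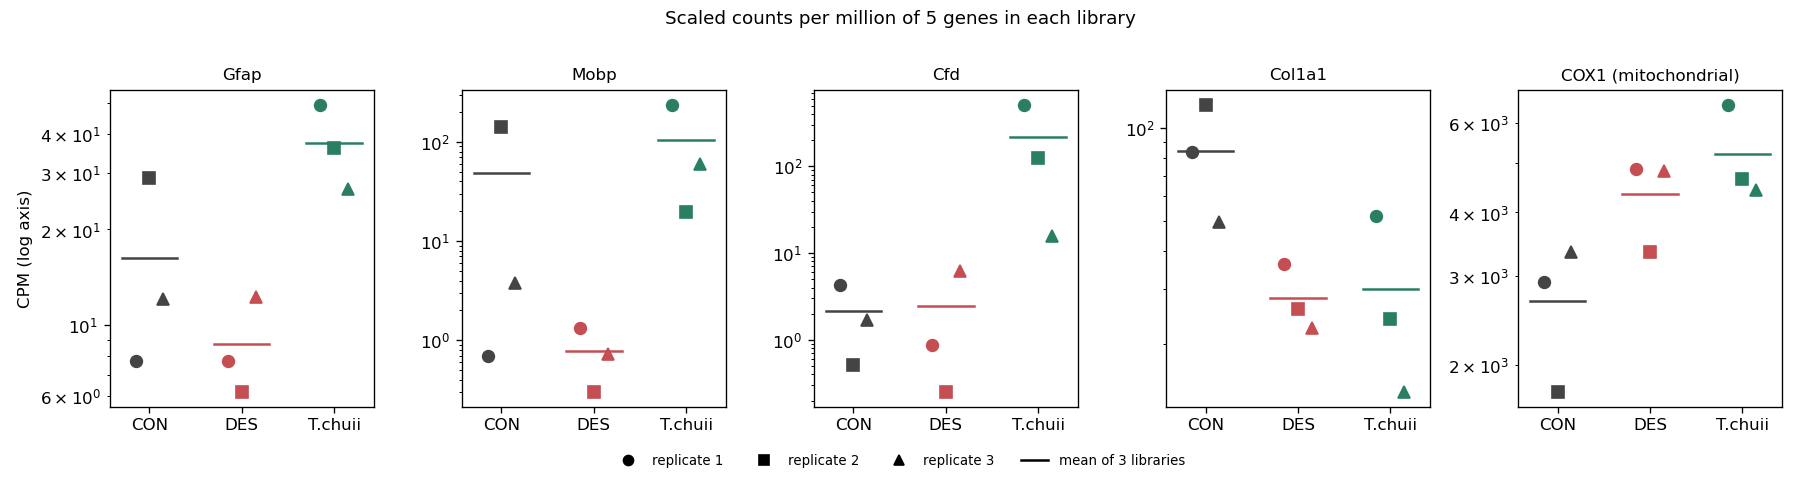
Scaled CPM (log axes, which differ between panels) of 5 genes in each of the 9 libraries, with points for libraries and lines for group means. Gfap averaged 37.4 CPM in T.chuii and 8.73 in DES, with CON between them at 16.3, and Mobp and Cfd varied widely within T.chuii.

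Gfap lies at chromosome 11, 102887336 to 102897200, Mobp at chromosome 9, 120149742 to 120181488, Cfd at chromosome 10, 79890853 to 79892655, and Fabp4 at chromosome 3, 10204342 to 10208616 (mm10). Further genes with higher means were the desaturase Scd1 (106 ± 79.5 against 19.1 ± 4.54 CPM), Thrsp, a regulator of lipid synthesis (153 ± 144 against 24.9 ± 11.3), the carbonic anhydrase Car3 (525 ± 556 against 87.8 ± 27.6), Cyp2e1 (55.4 ± 66.4 against 1.11 ± 1.17) and the angiotensinogen gene Agt (8.64 ± 2.33 against 4.22 ± 0.815). Lower means were seen for Chst12 (-0.97 ± 0.29), the dynein chain Dync1li1 (-0.94 ± 0.28), B4galt7 (-0.97 ± 0.32), Dohh (-0.91 ± 0.31), Tbcd (-1.26 ± 0.46), Cracr2b (-1.08 ± 0.37), Akr1c18 (-0.96 ± 0.35), Med18 (-0.97 ± 0.35), Ccdc166 (-0.77 ± 0.27) and Ereg, an epidermal growth factor receptor ligand (-0.86 ± 0.3). None of these passed the test.

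By list, all 6 adipocyte genes had higher means in T.chuii (median 2.68), and 5 passed when adjusted over the list alone against 0 over all genes (camera adjusted p = 3.32e-14, adjusted p = 0.149 with an estimated correlation). The list held 0.251%, 0.0621% and 0.0256% of reads in the T.chuii libraries and 0.0122%, 0.0101% and 0.0155% in DES. All 8 myelin genes had higher means, with Mbp at 326 ± 319 CPM against 48.3 ± 17.2 (camera adjusted p = 8.49e-08, adjusted p = 0.283 with an estimated correlation). All 19 fast muscle genes had higher means (median 1.27, camera adjusted p = 2.9e-15, adjusted p = 0.424 with an estimated correlation), for example Tnni2 at 1110 ± 851 against 382 ± 323. Of 14 Müller glia and astrocyte genes, 10 had higher means, and 1, Gfap, passed when adjusted over the list alone against 0 over all genes (camera adjusted p = 0.000155, adjusted p = 0.149 with an estimated correlation). Clu was at 2550 ± 361 CPM against 1760 ± 425 and Apoe at 2440 ± 502 against 1790 ± 312. Of 18 retinal stress and complement genes, Gfap among them, 14 had higher means (camera adjusted p = 2.81e-05, adjusted p = 0.51 with an estimated correlation, and 0.198 without T.chuii 1), where 16 had lower means in DES than in CON. Both comparisons share the DES libraries, so opposite directions arise in part without any effect. All 13 mitochondrially encoded genes had higher means (median 0.4, camera adjusted p = 0.000386, adjusted p = 0.644 with an estimated correlation), and that call was lost without T.chuii 1 (0.237) and without DES 2 (0.176).

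Glucocorticoid-responsive genes had higher means in 13 of 14 cases, with the clock gene Per1 at 10.4 ± 2.06 CPM against 5.8 ± 1.63 and Errfi1 at 85.8 ± 35.3 against 50.4 ± 4.9 (camera adjusted p = 1.15e-06, adjusted p = 0.424 with an estimated correlation). Macrophage and microglia genes were higher in 14 of 17 cases, with the complement gene C1qa at 24.5 ± 6.86 against 16.7 ± 2.78 (camera adjusted p = 2.58e-06, adjusted p = 0.424 with an estimated correlation), and pigment epithelium genes in 13 of 14, with Slc6a20a at 37.2 ± 3.48 against 25.2 ± 8.04 (camera adjusted p = 5.42e-06, adjusted p = 0.51 with an estimated correlation). Means were lower in T.chuii for all 16 cell cycle genes (median -0.53, camera adjusted p = 2.81e-05, adjusted p = 0.629 with an estimated correlation), such as Ccnb1 at 26.6 ± 15.4 against 48.4 ± 19.5. They were also lower for all 14 corneal epithelium genes (median -0.55, camera adjusted p = 9.51e-05, adjusted p = 0.629 with an estimated correlation) and for 17 of 20 interferon response genes (median -0.64, camera adjusted p = 0.000386, adjusted p = 0.67 with an estimated correlation). Calls were lost for glucocorticoid-responsive and macrophage genes without T.chuii 1 (camera adjusted p = 0.0713 and 0.121), for pigment epithelium genes without DES 1 (0.17), and for cell cycle and corneal epithelium genes without T.chuii 2 (0.275 and 0.214). Without T.chuii 2 the interferon list turned to the other direction (camera adjusted p = 0.892). The rod list, with 18 of 21 means lower in T.chuii (camera adjusted p = 0.0298, adjusted p = 0.841 with an estimated correlation), turned to the other direction without T.chuii 1 (0.00577). The crystallin list, with 6 of 6 means higher (camera adjusted p = 0.00693, adjusted p = 0.629 with an estimated correlation), turned to the other direction without DES 2 (0.0336).

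In the dry eye panel, Tnf was at 4.17 ± 1.83 CPM in T.chuii, Il1b at 1.85 ± 1.68, Ccl2 at 3.8 ± 2.26, Cxcl10 at 0.931 ± 0.619, Icam1 at 12.8 ± 6.13, Mmp9 at 3.3 ± 1.01, Mmp3 at 108 ± 26.7, Muc1 at 27.6 ± 2.14, Muc4 at 123 ± 35.1, Muc5ac at 17 ± 12.6, Krt12 at 10700 ± 8030, Aqp5 at 2570 ± 1890, Chrm3 at 1.7 ± 0.643, Hmox1 at 33.5 ± 32.6 and Nqo1 at 90.2 ± 34.9. None passed against DES. The cytokine list (10 of 21 higher, camera adjusted p = 0.987) and the antioxidant list (11 of 25 higher, 0.792) did not pass.

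In the T.chuii vs DES comparison limma-voom called 0 of 21287 genes at adjusted p 0.05, with 233 at an unadjusted p under 0.05, and limma-trend on FPKM called 0, with 277. The 233 were 1.09% of genes, below the share of 0.05 that unchanged genes would give on average. Groups did not overlap for 4.8% of genes, where chance gives 10%. Camera passed 19 of 42 lists, 14 higher and 5 lower in T.chuii, and 0 with an estimated correlation, while fry passed 0 (smallest adjusted p = 0.749). Of the 19 lists, 4 kept their call with each library left out in turn: fast muscle, adipocyte, myelin and Müller glia genes. With same-numbered DES and T.chuii libraries as pairs, a fit added after seeing the data, 2 genes passed, both higher in T.chuii: Mobp (log2 change 6.76 ± 0.3, adjusted p = 0.000421) and the muscle gene Nmrk2 (2 ± 0.18, adjusted p = 0.0391). Both calls rest on a pairing chosen from the same libraries.

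The comparison of T.chuii with CON sets the fed, injected mice against mice that were not injected. No single gene passed the test. Lens genes were again among those with the smallest p: Cryaa was at 21800 ± 15200 CPM in T.chuii and 4.41 ± 7.17 in CON (log2 change 14.12 ± 2.12), and Crybb1 at 1700 ± 1880 and 0.637 ± 0.511 (10.93 ± 2.41). The muscle actinin gene Actn3 was at 27.1 ± 12.9 against 4.19 ± 3.47, Fabp4 at 399 ± 485 against 14 ± 9.87, and the imprinted gene Nnat at 67.2 ± 11.6 against 16.3 ± 6.5. Lower means were seen for the transcription factor genes Junb (98.1 ± 49.3 against 264 ± 88 CPM) and Snai2 (18 ± 8.37 against 37.5 ± 9.53). All of these missed the threshold.

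Other genes with higher means were Adamts18 (2.44 ± 0.55), Cryba4 (9.12 ± 2.09), Retn (4.09 ± 0.95), Sept1 (2.89 ± 0.68) and Npl (1.62 ± 0.39), in log2 units. Lower means were found for Etv6 (-1.12 ± 0.34), Lgals7 (-1.32 ± 0.41), Chst12 (-0.95 ± 0.29), Lratd2 (-0.72 ± 0.23), Ptgs2 (-1.41 ± 0.45), Fkbp5 (-1.05 ± 0.36), Pwwp2b (-0.96 ± 0.35) and the pseudokinase gene Trib3 (-1.11 ± 0.4). None of these passed the test. In the dry eye panel no gene passed, the log2 changes of Mmp3 and Il1b being -0.85 ± 0.37 and -1.11 ± 0.57.

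All 19 fast muscle genes had higher means in T.chuii than in CON (median 2.35), and 18 passed when adjusted over the list alone against 0 over all genes (camera adjusted p = 1.05e-25, adjusted p = 0.263 with an estimated correlation). Acta1 was at 1250 ± 912 CPM against 190 ± 76.2 and Mylpf at 651 ± 497 against 99.6 ± 58. All 6 crystallins passed when adjusted over the list alone (camera adjusted p = 6.5e-15, adjusted p = 0.263 with an estimated correlation). All 13 mitochondrially encoded genes had higher means (median 1.02, camera adjusted p = 1.43e-12, adjusted p = 0.36 with an estimated correlation), with CYTB at 5590 ± 915 against 3050 ± 1210. All 14 corneal epithelium genes had lower means (median -0.91, camera adjusted p = 6.44e-07, adjusted p = 0.484 with an estimated correlation), among them Trp63, the epithelial progenitor factor, at 54.7 ± 28.4 against 105 ± 45.9. Of 16 matrix genes 13 had lower means, with the cornea proteoglycan gene Kera at 165 ± 154 against 417 ± 274 (camera adjusted p = 0.00027, adjusted p = 0.731 with an estimated correlation, and 0.079 without T.chuii 3). Of 18 immediate early genes 14 had lower means, with Zfp36 at 46.5 ± 27.2 against 117 ± 54.9 and Ier2 at 46.6 ± 14.9 against 101 ± 21.6 (camera adjusted p = 0.00302, adjusted p = 0.746 with an estimated correlation, and 0.459 without CON 1).

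In the T.chuii vs CON comparison limma-voom called 0 of 21287 genes at adjusted p 0.05, with 912 at an unadjusted p under 0.05, and limma-trend on FPKM called 0, with 1078. The 912 were 4.28% of genes, below the share of 0.05 that unchanged genes would give on average. Groups did not overlap for 8.4% of genes, where chance gives 10%. The count depended on the fit: 12 genes passed when only the 6 libraries of these groups were fitted, 17 without DES 2 and 2 with library weights, all higher in T.chuii and with lens genes among them (Cryaa, Cryab, Cryba4 and Crybb1 in the first 2 fits, Cryaa beside AA386476 in the last). Camera passed 18 of 42 lists, 11 higher and 7 lower, and 0 with an estimated correlation, while fry passed 0 (smallest adjusted p = 0.385). Of the 18 lists, 8 kept their call with each library left out in turn: both lens lists, both muscle lists, mitochondrially encoded, adipocyte, Müller glia and corneal epithelium genes.

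Whether T. chuii returned genes toward CON was examined from both contrasts that share DES. With 0 genes past the threshold in DES vs CON, no returning gene could be counted. Across genes, which are not independent replicates, the correlation of the 2 sets of log2 changes was 0.0013, against -0.5 in 100 simulated sets with no effect that shared DES. The covariance was 2e-04 against a simulated -0.1021, and opposite signs made up 51.3% of genes against a simulated 66.7%. The DES libraries were too few to be split between the contrasts, so part of the observed value may come from sharing them. Without DES 1 the correlation was -0.3215 and without DES 2 it was -0.2705, so single libraries moved it far. The simulation treated genes and libraries as independent, whereas the first principal component here held 37.1% of the variance. With genes that move together, a single set with no effect can lie far from -0.5, so the simulated values cannot judge the observed ones. If same-numbered DES and T.chuii libraries are pairs, as the correlation of their deviations (0.56, 0.34 and 0.17) leaves open, the value with no effect would lie above -0.5.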

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

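Counts of genes stayed at 0 in all 3 comparisons under median-of-ratios scaling, quantile normalization, removal of the lens crystallin, muscle and blood lists, no filter, the strict filter and no mean-variance trend. Fitting only the 6 libraries compared gave 12 genes for T.chuii vs CON, and library weights gave 2. Omission of single libraries gave 0 to 15 genes for DES vs CON and 0 to 17 for T.chuii vs CON, the higher values without DES 2, and 0 for T.chuii vs DES. The planned count tests were not run, and a pseudocount of 0.1 and FPKM in place of TPM did not apply to counts. The replicate block called 0 genes in each comparison and passed 18, 18 and 18 lists. Of 6 same-numbered pairs with CON, 2 had correlated deviations above 0.1, so the numbers were not taken as pairs there. Over all groups 4 of the 9 libraries correlated best with their own number. A replicate block on the DES and T.chuii libraries alone, added after seeing the data, called 2 genes and passed 20 lists, against 0 and 19.

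Added after seeing the data, the lens, muscle, cornea/rod, and cornea/rod with lens covariates, FPKM and unscaled totals gave 0 genes. Cornea/rod and muscle covariates gave 1 gene for T.chuii vs DES and 1 for T.chuii vs CON (Mobp), and with the lens covariate as well 2 and 2 (Mbp with Mobp, and Mbp with Gp2). Leaving out CON 2, DES 1 and T.chuii 1 together gave 1 and 1 (AA386476), with 0 for DES vs CON. The cause was not tested. Camera with an estimated correlation passed 0 lists in each comparison, against 18, 19 and 18.

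Omission of single libraries gave 15 to 21, 16 to 23 and 16 to 23 lists. Some lists that had passed turned direction, given here as ranges of the mean moderated t against other genes. For DES vs CON they were corneal epithelium (-1 to 0.06, highest without CON 2), endothelium (-0.21 to 0.99, lowest without DES 1) and ribosomal proteins (-0.33 to 1.12, lowest without DES 3). For T.chuii vs DES they were lens crystallins (-0.86 to 1.65) and other lens genes (-0.51 to 1.61), both lowest without DES 2, rods (-1.18 to 0.69, highest without T.chuii 1) and interferon response (-2.09 to 0.03, highest without T.chuii 2). For T.chuii vs CON it was erythroid genes (-0.12 to 2.11, lowest without T.chuii 1). In DES vs CON, fast muscle ranged from 0.6 to 2.35, mitochondrially encoded genes from 0.46 to 2.01 and the cytokine list from -0.83 to -0.1. Lists that kept their call with each library left out numbered 6 of 18, 4 of 19 and 8 of 18. Without CON 2, DES 1 and T.chuii 1 together, fast muscle (-0.05), slow muscle (-0.16) and endothelium (-0.01) turned in DES vs CON, and pigment epithelium (-0.23) and erythroid genes (-1.11) in T.chuii vs CON. The cause was not tested.

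The correlation of the contrasts that share DES ranged from -0.3215 (without DES 1) to 0.0851 over omitted libraries. Share comparisons without overlap numbered 4 to 6. Signs of named genes that had missed the threshold flipped for 0 of 303 values under median-of-ratios scaling, for 16 of 303 without CON 2, the most of any setting fixed beforehand, and for 78 of 303 with the 3 covariates together.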

Other observations

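Other tissue lists also differed between libraries. Myelin genes held 0.0968% of reads in CON 2 and 0.148%, 0.046% and 0.0682% in the T.chuii libraries, against 0.0283% to 0.0438% in the other 5. The 2 highest values, in CON 2 and T.chuii 1, were in libraries also rich in corneal transcripts. Hemoglobin and other erythroid genes held 0.259% in T.chuii 1 and at most 0.0939% elsewhere, with Hba-a1 and Hba-a2 nearly identical in sequence. Lists that passed camera and are not described above included, in DES vs CON, melanocyte genes (10 of 10 means lower, camera adjusted p = 0.000161, adjusted p = 0.44 with an estimated correlation), meibomian lipid genes (11 of 13 lower, 0.00182, adjusted p = 0.438 with an estimated correlation) and lymphocyte genes (8 of 8 higher, 0.0162, adjusted p = 0.405 with an estimated correlation). These calls were lost without DES 2 (0.128), CON 3 (0.723) and CON 1 (0.454), in that order. In T.chuii vs CON they included adipocyte genes (5 of 6 higher, 6.44e-07, adjusted p = 0.263 with an estimated correlation), cell cycle genes (15 of 16 lower, 0.000326, adjusted p = 0.746 with an estimated correlation) and interferon response genes (19 of 20 lower, 0.00332, adjusted p = 0.746 with an estimated correlation). The calls of the last 2 were lost without CON 2 (0.239) and T.chuii 2 (0.896). Lists of heat shock genes (camera adjusted p = 0.872, 0.762 and 0.898 in DES vs CON, T.chuii vs DES and T.chuii vs CON), the unfolded protein response (0.0566, 0.909 and 0.224), the circadian clock (0.419, 0.909 and 0.502), cholinergic genes (0.872, 0.244 and 0.497), lacrimal gland (0.982, 0.28 and 0.421) and neutrophil genes (0.982, 0.316 and 0.447) did not pass in any comparison.

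The remaining lists that passed are given with the count of means, the camera adjusted p and the adjusted p with an estimated correlation. They were, in DES vs CON, other lens genes (9 of 9 higher, 8.17e-11, 0.405), slow muscle (14 of 15 higher, 8.51e-07, 0.468), endothelium (10 of 12 higher, 0.0165, 0.685), ribosomal proteins (21 of 25 higher, 0.0453, 0.915), immediate early genes (16 of 18 lower, 0.00182, 0.606), macrophage genes (15 of 17 lower, 0.015, 0.685) and hair follicle genes (5 of 6 lower, 0.0162, 0.405). Calls were lost for slow muscle without DES 1 (camera adjusted p = 0.144), and for ribosomal proteins and immediate early genes without CON 1 (0.542 and 0.638). Without CON 3 they were lost for endothelium (0.444), macrophage genes (0.334) and hair follicle genes (0.334). They were, in T.chuii vs DES, other lens genes (8 of 9 higher, 0.00616, 0.629), slow muscle (14 of 15 higher, 1.09e-07, 0.51), smooth muscle (10 of 10 higher, 0.00892, 0.644), meibomian lipid genes (6 of 13 higher, 0.0346, 0.629) and cornification (10 of 14 lower, 0.0129, 0.424). The call of other lens genes was lost without T.chuii 2 (camera adjusted p = 0.722) and with the replicate block on DES and T.chuii libraries alone (0.0799). That of meibomian lipid genes was lost without T.chuii 1 (0.633), DES 2 (0.176), DES 3 (0.12) and CON 2 (0.0703). It was also lost with the replicate block on all libraries (0.0541). Calls were also lost for slow muscle without T.chuii 1 (0.181), smooth muscle without DES 3 (0.908) and cornification without T.chuii 2 (0.692). They were, in T.chuii vs CON, other lens genes (9 of 9 higher, 6.42e-10, 0.263), slow muscle (14 of 15 higher, 3.15e-13, 0.31), myelin (7 of 8 higher, 0.00272, 0.484), pigment epithelium (13 of 14 higher, 0.00614, 0.746), Müller glia (11 of 14 higher, 0.00641, 0.263), endothelium (10 of 12 higher, 0.016, 0.746), erythroid genes (5 of 5 higher, 0.0229, 0.746), cornification (11 of 14 lower, 0.00302, 0.263) and ion and water transport (13 of 15 lower, 0.00302, 0.544). Calls were lost for myelin without T.chuii 1 (camera adjusted p = 0.275), endothelium without CON 3 (0.249) and cornification without T.chuii 2 (0.083). Without CON 2 they were lost for pigment epithelium (0.625), erythroid genes (0.192) and ion and water transport (0.0962).

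Of the tests that follow, those on lens genes, Müller glia, the myelin covariate, the collagen difference, the gene counts of other splits and the division of splits by pairs were chosen after the values were seen. The tests without lens, muscle and blood lists, and the list counts of other splits, were written before their results were seen.

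Lens genes were high in 5 of 9 libraries, none of them CON. The 15 lens genes moved together, with a median pairwise correlation of 0.93 over libraries, as different amounts of lens tissue in the samples would give, and as joint regulation of lens genes would give too. No CON library was rich in lens reads (highest CON share 0.0083 of the second-lowest DES share), but if lens reads follow dissection, DES 2 may have been exchanged with a lens-poor CON library, so this stays open. A rise in every injected eye stays open: 0 of the 6 injected libraries lay within the bound set from CON of 0.037%, but DES 2 cleared it narrowly at 0.0408%, against 3.47% and 4.07% in the other DES libraries. Lens amount and injection cannot be separated by these tables, and whether lenses were kept in all samples is not given in the sources used here.

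Gfap was higher in T.chuii than in DES by 2.14 ± 0.46 log2 units. The other Müller glia genes had a median change of 0.18 (SD 0.23), so a larger share of Müller glia would not account for the whole Gfap change. A larger share itself stays open. The list held 0.789% ± 0.0823 of reads in T.chuii and 0.61% ± 0.0533 in DES (SD, n = 3), and these groups did not overlap. This comparison of shares was not planned, and its exact permutation p was 0.1, the smallest possible. Without the lens crystallin, muscle and blood lists the Gfap change was 2.15 ± 0.46. The median change of all genes moved only from -0.03 to -0.025, so the removal could hardly have moved the Gfap change. It leaves other distortions of the scaling untested. Under median-of-ratios scaling the sign of Gfap was kept, as 0 of 303 values of named genes flipped. With the mean myelin value as a covariate the Gfap change was 1.2 ± 0.43. More optic nerve tissue in the T.chuii samples may thus account for part of it, and this cannot be told apart from a glial response with 3 libraries per group.

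Matrix genes had lower means in DES than in CON, and the list median was -0.72 (SD 0.5) without the lens crystallin, muscle and blood lists. The median change of all genes moved only from -0.016 to -0.01, so the removal could hardly have moved the list median. In 13 of 13 other settings the list passed camera in the lower direction. Median-of-ratios scaling and quantile normalization were among them, so these scalings did not remove the lower means. Less corneal stroma and sclera would lower collagens and other matrix genes alike. Their difference changed by -0.65 ± 0.41 log2 units between the groups, so this explanation cannot be told apart from a change in collagen transcripts, because the difference was under 2 standard errors.

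Each comparison allows 10 splits of its 6 libraries, too few for a share under 0.05. The gene counts were 0, 0 and 0 in DES vs CON, T.chuii vs DES and T.chuii vs CON, with highest counts in other splits of 0, 0 and 1, and all 10 splits gave at least as many in each, which a count of 0 fixes beforehand and which says nothing about chance. List counts were 18, 19 and 18, with highest counts in other splits of 17, 24 and 22, and 1, 7 and 5 of the 10 splits gave at least as many. Of the 4 splits of T.chuii vs DES that part every same-numbered pair, 3 gave at least 19 lists, the real one included, and the other 6 splits gave up to 24 lists and 4030 genes at an unadjusted p under 0.05, against up to 703 in the first 4. At an unadjusted p under 0.05, the real splits gave 235, 233 and 912 genes. Splits of the same libraries that mixed the groups gave 233 to 1816, 114 to 4030 and 199 to 2980. The real counts thus lay within the range of the mixed splits in each comparison. The highest of several mixed splits can exceed 1 real split by chance, so no conclusion is drawn from these maxima.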
